A study of Mus musculus with 6 samples.

How the data were processed

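Small RNA libraries from mouse embryonic fibroblasts were sequenced, 3 from wild-type (WT) cells and 3 from cells in which Fbxw7 was knocked out (Fbxw7 KO). The labels give the genotype of each library and a number from 1 to 3 within each genotype. Nothing in the labels says whether the libraries of a genotype came from separate embryos or cultures, so the p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, RNA was taken from cultured cells with Trizol and a column kit, and libraries were made with the Illumina TruSeq small RNA chemistry.

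The main table holds whole-number read counts per miRNA gene name, and per the file headers the authors made these counts with featureCounts 1.6.4, grouped by gene name and with strand ignored. The recorded command switches on neither the counting of reads with several alignments nor that of reads over 2 features, and both kinds are left out by the program's default. A hairpin with a near-identical copy elsewhere, or one that overlaps another annotated row, can therefore lose counts or stand at 0, and values of such rows are uncertain. Among the miRNAs named, this holds also for Mir16-2, Mir23a, Mir27a, Mir27b, Mir128-1, Mir146, Mir181a-1, Mir194-2, Mir199b, Mir487b and Mirlet7a-2, which each share at least 20 bases with another row. Both arms of a hairpin fall into 1 value. Per the submitters' processing notes, the genome build was mm10 and the tools included TopHat2 2.1.1, SAMtools 1.5, Cufflinks 2.2.1 and deepTools. Adapter trimming, read length limits and the part each tool played are not given in the sources used here.

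A second table holds FPKM values deposited by the authors. In all 1155 rows these equal the count divided by feature length and by the library total times an edgeR TMM factor, within a relative difference of 1e-06. They are thus the counts on another scale and were used only in alternatives. Of the 1155 rows, 1137 have a miRNA gene of the same name in GENCODE M21, and 1133 of those (99.6%) have the same coordinates and strand. Positions below are those of the count table, on mm10, and host genes come from GENCODE M21.

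Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, TMM factors), 2-sided, with genotype as the only term. The filterByExpr function with its minimum count of 10 and minimum total of 15 left 283 of the 1155 rows for testing. Adjusted p-values are Benjamini-Hochberg values from this test over the 283 rows, with a threshold of 0.05, and the SE of a log2 fold change was taken from the F statistic. CPM values use the TMM-scaled library totals and are given as mean ± SD with n = 3 libraries per genotype.

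Lists of miRNAs were fixed before the data were examined. They are the miR-17, miR-106b and miR-106a clusters, let-7 and miR-98, miRNAs repressed by Myc, p53-induced miRNAs, the Dlk1-Dio3 cluster, the Sfmbt2 intronic cluster, the X-linked miR-322 cluster, Hox cluster miRNAs, the miR-232724 clusters, the miR-183 cluster (Mir183, Mir96 and Mir182), miRNAs reported to target Fbxw7, inflammatory miRNAs, and the miR-29, miR-30, miR-15/16, miR-181 families, and the miR-130, miR-301, miR-148 and miR-152 families together. The fibroblast list stands for the main cell type, and muscle, blood cell, epithelial, neuronal, endothelial, liver and pluripotent cell lists stand for others. The 19 of the 25 lists with at least 3 tested members were compared with all other tested miRNAs by camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 19. Lists share members, so their results are not independent.

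The miRNAs named in the text follow a rule set before the data were examined. Among those past the threshold, with KO and WT libraries that do not overlap and a mean of at least 10 CPM, it takes the 12 largest rises and the 12 largest falls. It adds the 5 most abundant miRNAs and, for each list described, up to 4 changed members with the lowest p, or the 2 most abundant members where none changed. Mir216a, Mir127, Mir540, Mir494, Mir1193, Mir487b, Mir496a, Mir25, Mir10b, Mir196a-1, Mir345 and Mir434 lie outside this rule and were picked after their values were seen, as were the examples of rows at 0 and of neighbouring hairpins. The share of counts in the 10 most abundant miRNAs was compared with an exact 2-sided permutation test, in which 3 against 3 libraries cannot give a p under 0.1.

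The libraries held 2932439 to 5019700 counts. Counts simulated from the means and library sizes of this comparison, with 200 rows changed, left 286 rows tested. The edgeR test recovered 28.1% of the tested rows changed 1.5-fold, 78.6% of those changed 2-fold and 100% of those changed 4-fold, with 0 false calls among 46. In 20 simulated runs without any change, each filtered anew, 2 had a list past the threshold. This simulation drew each miRNA independently, so it does not cover lists whose members vary together.

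The alternatives were DESeq2 1.42.0 size factors or its Wald test, library totals or upper quartile factors, no filter or a stricter one (at least 10 CPM in 3 libraries), limma-voom, a replicate block, leaving out each library, removing the 5 most abundant miRNAs, and summing copies of a mature miRNA. Limma was also run on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM, with a minimum of 30 FPKM in 3 libraries or none, and list tests were repeated with an estimated correlation and with fry. Figures were drawn with matplotlib 3.10.9. The Fbxw7 transcript itself was not analysed here, so the genotype labels have no check from the values.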

Results

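The series profiled miRNAs in mouse embryonic fibroblasts, primary connective tissue cells cultured from embryos, to compare cells that have Fbxw7 with cells in which it was knocked out. FBXW7 is the substrate-recognition subunit of an SCF ubiquitin ligase that marks Myc, cyclin E, Jun and Notch for degradation. There were 3 WT and 3 Fbxw7 KO libraries. WT replicates 1 to 3 held 5019700, 4568352 and 3707576 counts, and Fbxw7 KO replicates 1 to 3 held 3140258, 2932439 and 3753353. Between 484 and 532 of the 1155 annotated rows had counts in a library. The Fbxw7 transcript was not analysed here.

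A small number of miRNAs made up most of the counts in both genotypes. Mir21a, encoded in an exon of Vmp1 on chromosome 11, held 24.01% ± 1.33 of counts in WT and 27.6% ± 0.797 in Fbxw7 KO (SD, n = 3), and Mir143, a smooth muscle and mesenchymal miRNA on chromosome 18, held 22.2% ± 1.55 and 22.6% ± 0.877. Neither passed the test between genotypes (log2 fold change 0.15, edgeR adjusted p = 0.338 for Mir21a; −0.03, adjusted p = 0.883 for Mir143). The same was found for Mir27b (−0.04, adjusted p = 0.895) and Mir148a (0.11, adjusted p = 0.643), and the small values of Mir143, Mir27b and Mir148a changed sign under other scalings. Mir10a, the fourth most abundant, was lower in Fbxw7 KO. The 10 most abundant miRNAs together held 74.7% ± 0.417 of counts in WT and 73.7% ± 0.39 in Fbxw7 KO, a difference in the share of counts in the 10 most abundant miRNAs of −1.03 percentage points (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give).

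Loss of Fbxw7 was accompanied by higher Mir217, Mir672, Mir210, Mir708 and Mir31, and by lower Mir96, Mir183, Mir182, Mir615 and Mir10a. In all, 72 of the 283 tested miRNAs changed, 43 higher and 29 lower in Fbxw7 KO (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 20 rose and 7 fell by 2-fold or more. In 71 of the 72 the 3 KO libraries did not overlap the 3 WT libraries. Among all 283 tested miRNAs this held for 43.8%, where chance gives 10%. The first principal component held 65.2% of the variance and separated the genotypes, and the second held 17.5% and set Fbxw7 KO replicate 3 (score −6.45) apart from replicates 1 and 2 (2.9 and 3.54). Counts of changed miRNAs were 42 without WT replicate 1, 35 without WT replicate 2 and 66 without WT replicate 3. They were 48 without Fbxw7 KO replicate 1, 34 without Fbxw7 KO replicate 2 and 78 without Fbxw7 KO replicate 3, the library set apart. With TMM factors taken from miRNAs outside the Dlk1-Dio3 cluster, chosen after seeing the data, 29 were higher and 34 lower, and the median log2 fold change of all tested miRNAs moved from 0.05 to −0.08.

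**Figure D1:**
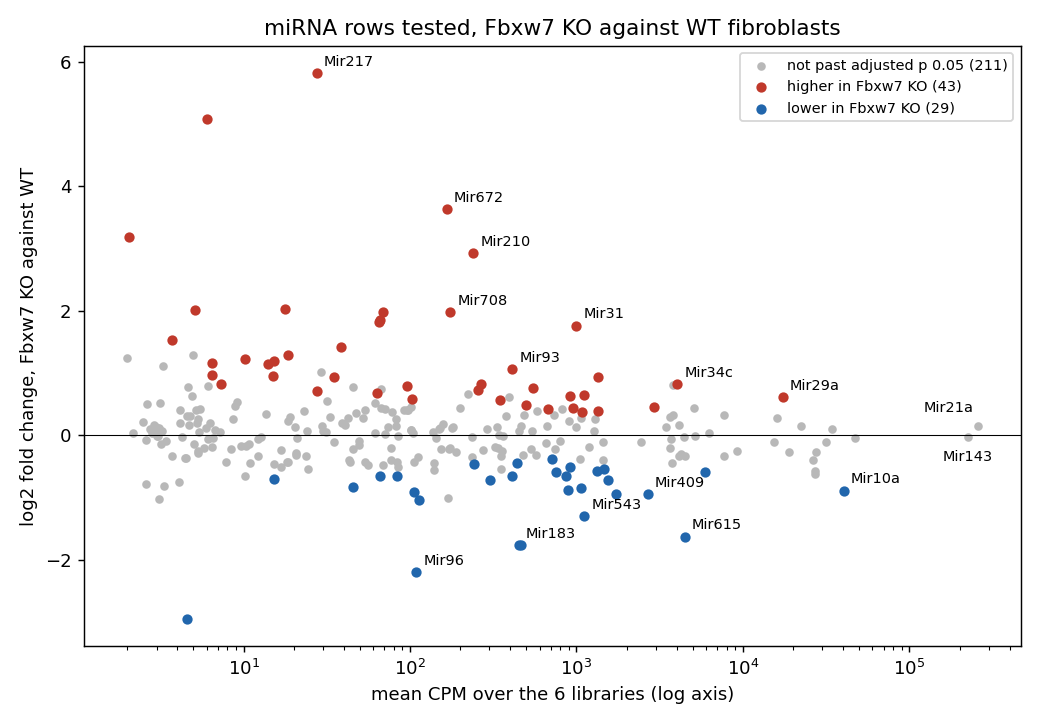
Log2 fold change of each of the 283 tested miRNAs (Fbxw7 KO against WT, n = 3 each) against its mean CPM over the 6 libraries on a log axis. Red points are the 43 miRNAs higher in Fbxw7 KO and blue points the 29 lower. Mir217 stands at 5.82, and Mir96, the largest fall at a mean of at least 10 CPM, at −2.20. The most abundant, Mir21a and Mir143, lie near 0.

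The largest rise was that of Mir217, which lies in an intron of the lincRNA gene Gm12082 (chromosome 11, 28763728 to 28763835, plus strand) and is known as a pancreatic miRNA. It had 0.924 ± 0.23 CPM in WT and 54.1 ± 32.4 CPM in Fbxw7 KO, a log2 fold change of 5.82 (SE 0.669, edgeR adjusted p = 0.000666). Fbxw7 KO replicates 1 and 2 had 69.7 and 75.8 CPM and replicate 3 had 16.9. WT held only 12 counts in all against 510 in Fbxw7 KO, a ratio of shares of 57.5 (95% interval 32.6 to 112, counting error only). Its neighbour Mir216a had 4 WT and 110 Fbxw7 KO counts, a ratio of 37.2 (95% interval 14.1 to 139, counting error only), and a log2 fold change of 5.09 (SE 0.841, edgeR adjusted p = 0.00293). Fbxw7 KO replicates 1 to 3 held 50, 49 and 11 of the Mir216a counts.

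Mir672, in an intron of Nexmif (chromosome X, 104116175 to 104116274, minus strand), went from 24.5 ± 10.2 CPM in WT to 307 ± 40.4 CPM in Fbxw7 KO, a log2 fold change of 3.64 (SE 0.303, edgeR adjusted p = 0.000227). Mir210, the miRNA best known for its induction by hypoxia-inducible factors (chromosome 7, 141221384 to 141221493, minus strand), went from 55.4 ± 15.0 to 423 ± 156 CPM (log2 fold change 2.93, SE 0.304, adjusted p = 0.000666). Mir31 (chromosome 4, 88910557 to 88910662, minus strand, in an exon of a lincRNA gene) was more abundant, with 454 ± 111 CPM in WT and 1544 ± 215.4 in Fbxw7 KO (1.77, SE 0.194). Smaller pools rose by like amounts: Mir708 in an intron of Tenm4 (1.98, SE 0.266), Mir592 in an exon of Grm8 (1.85, SE 0.284) and Mir582 in an intron of Pde4d (1.83, SE 0.21). The remaining miRNAs among the 12 largest rises under the naming rule were Mir344b (2.02), Mir3535 (1.42), Mir195a (1.30), Mir378c (1.23) and Mir344d-3 (1.19). Mir344b, Mir344d-3 and Mir378c share sequence with copies elsewhere, so their counts are uncertain. Mir3535, in an exon of Ncl, lost its call without WT replicate 1, WT replicate 3 or Fbxw7 KO replicate 2 (adjusted p up to 0.0803), Mir195a without WT replicate 1 (0.0803), and Mir344d-3 without WT replicate 1, Fbxw7 KO replicate 1 or Fbxw7 KO replicate 2 (up to 0.0834).

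All 3 members of the miR-183 cluster (Mir183, Mir96 and Mir182), which is transcribed as 1 unit and is best known from sensory organs, fell. They lie within 30165918 to 30169737 of chromosome 6, minus strand. Mir96 fell from 178 ± 63.9 to 39.0 ± 7.42 CPM (log2 fold change −2.20, SE 0.298, edgeR adjusted p = 0.00114), Mir183 from 692 ± 231 to 204.9 ± 50.7 CPM (−1.76, SE 0.283, adjusted p = 0.00268) and Mir182 from 716 ± 306 to 211 ± 78.1 CPM (−1.76, SE 0.4, adjusted p = 0.0169). WT replicate 3 was the lowest WT library for all 3, at 104.5, 429.5 and 367.1 CPM, still above every Fbxw7 KO library. Mir182 lost its call without WT replicate 1, without Fbxw7 KO replicate 2 and with no filter on low values in counts or FPKM (adjusted p up to 0.169). Adjusted over the list alone, all 3 were also lower. The list test gave camera adjusted p = 0.000885 with the preset correlation and adjusted p = 0.594 with an estimated correlation.

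Of the 5 tested miRNAs encoded in the Hox clusters, 3 fell, and likewise 3 when adjusted over the list alone. Mir615, in an intron of Hoxc5 (chromosome 15, 103014910 to 103015001, plus strand), fell from 6761 ± 2050 to 2192 ± 135.7 CPM (log2 fold change −1.62, SE 0.216, edgeR adjusted p = 0.00114). Mir10a, beside the Hoxb genes (chromosome 11, 96317165 to 96317274, plus strand), fell from 52210 ± 6480 to 28230 ± 1769 CPM (−0.89, SE 0.131, adjusted p = 0.00179). Mir196a-2, in the Hoxc cluster, fell from 2265 ± 103 to 1180 ± 219.2 CPM (−0.94, SE 0.153, adjusted p = 0.00275), with the reservation that it shares sequence with Mir196a-1 (−0.22, adjusted p = 0.409). Mir10b, beside the Hoxd genes, had a log2 fold change of 0.27 (adjusted p = 0.275). The list held 7.43% ± 0.409 of counts in WT and 5.01% ± 0.226 in Fbxw7 KO (exact permutation p = 0.1, the smallest possible). The camera adjusted p was 0.0161 with the preset correlation, and adjusted p = 0.594 with an estimated correlation. The estimate for this list was −0.0343, lower than the preset value, yet the unadjusted camera p rose from 0.00255 to 0.0361. Members that vary together therefore do not account for the lost call of this list.

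**Figure D2:**
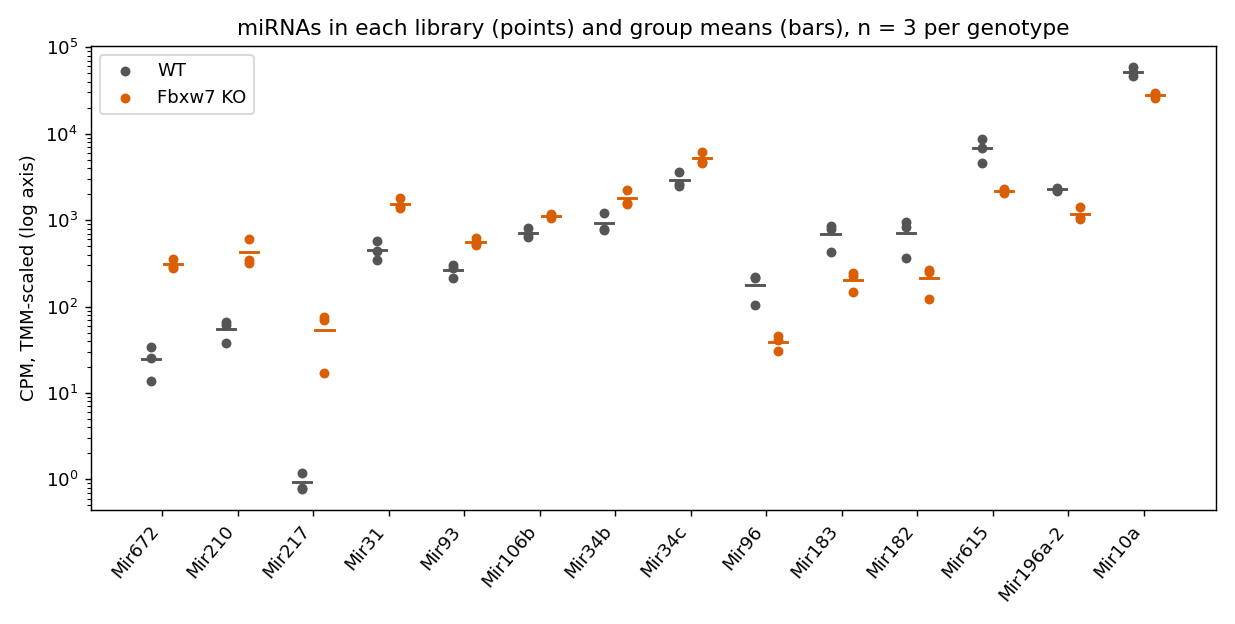
CPM of 14 miRNAs in each library on a log axis, with points for single libraries and bars for the mean of each genotype (n = 3). The 3 Fbxw7 KO libraries lie above the 3 WT libraries for Mir672, Mir210, Mir217, Mir31, Mir93, Mir106b, Mir34b and Mir34c and below them for Mir96, Mir183, Mir182, Mir615, Mir196a-2 and Mir10a.

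The list of the Dlk1-Dio3 imprinted cluster on chromosome 12, whose miRNAs are made from the maternal chromosome, gave the most falls of any list. It also had the most tested members. The list includes Mir345, which lies apart from the others in an exon of the protein-coding gene Slc25a47. Of its 42 tested members 16 fell, 0 rose and 26 did not pass the test, with the same counts adjusted over the list alone, and 38 of the 42 had a negative log2 fold change (median −0.46). Mir543 fell from 1573 ± 204 to 643 ± 111 CPM (log2 fold change −1.29, SE 0.167, edgeR adjusted p = 0.00108), Mir409 from 3529 ± 400 to 1837 ± 131.8 CPM (−0.94, SE 0.136, adjusted p = 0.00165) and Mir341, in an intron of Rian, from 1143 ± 13.5 to 623 ± 42.6 CPM (−0.88, SE 0.113, adjusted p = 0.00108). Mir433, antisense to Rtl1 in a count that ignored strand, had a log2 fold change of −0.66 (SE 0.115). Mir770 in Meg3 (−1.04, SE 0.202), Mir668 (−0.90, SE 0.187) and Mir495 (−0.84, SE 0.173) also fell, and Mir668 overlaps the Mirg row, which makes its count uncertain. The 4 members with positive values were Mir494 (0.32, adjusted p = 0.178), Mir487b (0.08), Mir496a (0.09) and Mir1193 (0.00). The list held 15.8% ± 1.28 of counts in WT and 11.9% ± 3.64 in Fbxw7 KO (exact permutation p = 0.2), with 7.86% in Fbxw7 KO replicate 3. Without Mir127 it held 12.6% ± 0.526 and 9.75% ± 1.83 (exact permutation p = 0.1, the smallest possible). Fbxw7 KO replicates 1 to 3 then stood at 10.97%, 10.63% and 7.644%. Mir127, its most variable member, had 2082 CPM in Fbxw7 KO replicate 3 against 19200 and 42820 in the other KO libraries (adjusted p = 0.722). The camera adjusted p was 8.21e-09 with the preset correlation, and adjusted p = 0.594 with an estimated correlation. The same list also passed the preset test in 6 of the 9 other divisions of the 6 libraries into 3 and 3, with medians of at most 0.28 in size. The camera adjusted p was 7.39e-09 with WT replicates 1 and 3 and Fbxw7 KO replicate 2 as 1 group. It was 4.03e-09 with WT replicate 1 and Fbxw7 KO replicates 1 and 3 as 1 group. Both lie below the 8.21e-09 of the real division, so this p does not set the genotypes apart.

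**Figure D3:**
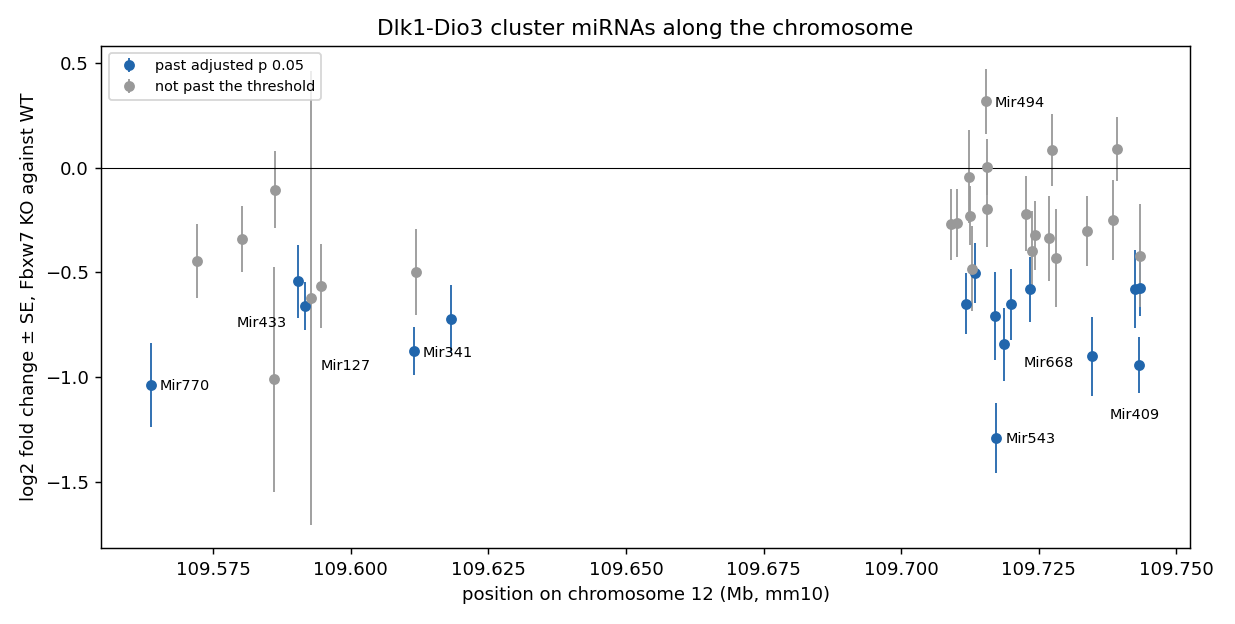
Log2 fold change (Fbxw7 KO against WT, n = 3 each) of 41 Dlk1-Dio3 miRNAs by position on chromosome 12 in Mb (mm10), with bars for ± SE; the outlying Mir345 (−0.18) is not drawn. Blue points are the 16 that fell, spread over both parts of the cluster, and the long bar on Mir127 reflects its spread between libraries.

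Of the miR-17 cluster and its paralogs, the miR-106b and miR-106a clusters, which Myc and E2F factors activate, 4 members could be tested. Among these 2 rose and 0 fell, or 3 and 0 adjusted over the list alone, and 8 of the 15 rows of the list stood at 0 counts, among them the miR-17 cluster hairpins, whose rows overlap that of their host transcript. Mir93, in Mcm7 (chromosome 5, 138165523 to 138165610, minus strand), rose from 267 ± 45.65 to 558 ± 52.95 CPM (log2 fold change 1.07, SE 0.162, edgeR adjusted p = 0.00211). Mir106b beside it rose from 715 ± 86.4 to 1111 ± 57.7 CPM (0.64, SE 0.129, adjusted p = 0.00909, and 0.0522 without Fbxw7 KO replicate 2). The list did not pass the camera test (adjusted p = 0.0506, and adjusted p = 0.594 with an estimated correlation), but did in 8 of 18 alternatives (range 0.0123 to 0.594).

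In the p53-induced list 4 of 7 tested members rose and 0 fell, also when adjusted over the list alone. Mir34b and Mir34c, made from 1 transcript that p53 activates, went from 927 ± 254 to 1784 ± 385 CPM (log2 fold change 0.94, SE 0.219, edgeR adjusted p = 0.0161) and from 2920 ± 635 to 5167 ± 875 CPM (0.82, SE 0.188, adjusted p = 0.0154). They lie antisense to Btg4, within an intron, and strand was ignored in counting. Both calls ended without WT replicate 1 or WT replicate 2 (adjusted p up to 0.0769 and 0.0719). Mir34a (0.49, adjusted p = 0.0365) and Mir194-2 (0.59, adjusted p = 0.0347) rose by less, and their calls ended in 7 and 6 of 21 alternatives. The list did not pass the camera test (adjusted p = 0.134), but passed in 2 of 18 alternatives (adjusted p range 0.00878 to 0.594).

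Of 6 tested miR-15/16 family members, which share a seed and repress cyclins, 4 rose and 0 fell, also when adjusted over the list alone. Mir15b and Mir16-2, together in an intron of Smc4, had log2 fold changes of 0.83 (SE 0.182, edgeR adjusted p = 0.0133) and 0.80 (SE 0.195, adjusted p = 0.0181), and Mir15a had 0.72 (adjusted p = 0.0416). Mir15b lost its call without WT replicate 2, Mir16-2 without WT replicate 2 or Fbxw7 KO replicate 2, and Mir15a in 8 of 21 alternatives. The camera adjusted p of the family was 0.0564, and it fell below 0.05 in 9 of 18 alternatives (range 0.00124 to 0.697). In the miR-29 family 1 of 3 tested members rose and the others did not pass, also when adjusted over the list alone. That member, Mir29a, a repressor of collagen genes, went from 13650 ± 852.5 to 20930 ± 1300 CPM (0.62, SE 0.122, adjusted p = 0.00789, and 0.0512 without Fbxw7 KO replicate 2). The camera adjusted p of the family was 0.549, and of 17 alternatives only 1, fry, fell below 0.05 (range 0.0265 to 0.748).

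Of 14 tested miRNAs that Myc is known to repress, 4 rose, namely Mir29a, Mir195a, Mir34a and Mir15a, 0 fell and 10 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.134). This list passed in 2 of 18 alternatives (adjusted p range 0.00878 to 0.697). In the let-7 and miR-98 family, which Myc also represses, 1 of 10 tested members fell, Mirlet7a-2 (log2 fold change −0.38, edgeR adjusted p = 0.0419), and 0 passed adjusted over the list alone. That call ended in 13 of 21 alternatives, and the camera adjusted p was 0.837. Of 7 tested miRNAs reported to target Fbxw7 itself, Mir182 and Mir32 fell (Mir32 −0.65, SE 0.166, adjusted p = 0.0207, and up to 0.0864 over 4 leave-outs), and adjusted over the list alone Mir25 (0.81) was also called, as higher (camera adjusted p = 0.794).

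Among the 17 tested fibroblast and mesenchymal miRNAs, Mir31 and Mir199b rose, Mir10a fell and 14 did not pass, also when adjusted over the list alone. Mir199b, antisense to Dnm1, had a log2 fold change of 0.65 (SE 0.165, edgeR adjusted p = 0.0203, and up to 0.0736 without WT replicate 2 or Fbxw7 KO replicate 2). This list held 64.9% ± 0.787 of counts in WT and 67.0% ± 3.32 in Fbxw7 KO (exact permutation p = 0.4, camera adjusted p = 0.837). Markers of other cell types are measured only in part, since 7 of 10 muscle, 10 of 14 pluripotent cell, 5 of 17 neuronal, 3 of 7 blood cell and 2 of 2 endothelial rows stood at 0 counts. Several of these overlap another row (Mir1a-2, Mir142, Mir126a and Mir292 among them), and reads over both are left out in counting, so their shares are no measure of these cells. Muscle miRNAs held 0.0176% of counts in WT and 0.0285% in Fbxw7 KO, with Mir206 at 390 CPM in Fbxw7 KO replicate 3 against 137.3 to 220.9 in the others (adjusted p = 0.11) and Mir499 at 4.38 and 5.01 CPM. Neuronal miRNAs held 0.0584% and 0.0494%, with Mir132 at a log2 fold change of −0.53 (adjusted p = 0.0701), Mir128-1 at 0.10 and a camera adjusted p of 0.873. Epithelial miRNAs held 0.00235% and 0.00441%, where Mir203, the only tested member, had 59.3, 45.5 and 13.3 CPM in Fbxw7 KO against 18.7 to 19.97 in WT (adjusted p = 0.133). It counted as higher over the list alone, but with 1 tested member that is the unadjusted edgeR p of 0.0469. The liver miRNA Mir122 had a log2 fold change of −0.23 (adjusted p = 0.703). Blood cell miRNAs held 0.000291% and 0.000225% and pluripotent cell miRNAs 2.23e-05% and 2.84e-05%, while both endothelial rows were listed at 0. In the muscle, neuronal and liver lists 0 members passed the edgeR test, adjusted over the list alone included.

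The other lists had at most 1 changed member each. Mir23a of the miR-232724 clusters rose from 2476 ± 80.0 to 3404 ± 271 CPM (log2 fold change 0.46, SE 0.122, edgeR adjusted p = 0.0251, and up to 0.115 over 4 alternatives that ended the call), and 3 other members did not pass (camera adjusted p = 0.986). Mir148b of the miR-130, miR-301, miR-148 and miR-152 families had 0.40 (adjusted p = 0.0465), which 13 of 21 alternatives and the adjustment over the list alone did not keep (camera adjusted p = 0.986). No member passed, in either adjustment, in the Sfmbt2 intronic cluster (Mir669c −0.43 and Mir467d −0.28, both sharing sequence with many copies; camera adjusted p = 0.709), the X-linked cluster (Mir322 0.27, Mir351 −0.32; 0.837), the inflammatory list (Mir21a 0.15, Mir146 −0.00; 0.837), the miR-30 family (Mir30d −0.25, Mir30a 0.03; 0.862) or the miR-181 family (Mir181d −0.32, Mir181a-1 0.45; 0.986). The values of Mir146, Mir30a and Mir128-1 changed sign under other scalings.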

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

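The tests that thinned the libraries, took scaling factors outside the Dlk1-Dio3 cluster or left Mir127 out of that list were chosen after the data were seen. Of the 24 miRNAs with the largest changes, 20 kept their direction and call in all their alternatives, 21 each and 20 for Mir10a, and Mir182, Mir3535, Mir195a and Mir344d-3 did not. Of the 17 other named miRNAs with a call, 3 did so (Mir93, Mir433 and Mir216a). Calls numbered 72 with the DESeq2 Wald test (66 shared with the 72), 68 with limma-voom (68 shared), 71 with DESeq2 size factors (70 shared), 69 with library totals, 68 with upper quartile factors and 70 without a filter (60 shared). They numbered 56 with the stricter filter, where 19 were lower instead of 29 and fewer rows were tested, and 60 with every library thinned to the smallest total. Leaving out 1 library at a time gave 34 to 78 changed miRNAs, 19 to 46 higher and 15 to 32 lower, and fewer samples lower what a test can reach. The share of counts in the 10 most abundant miRNAs, with those 10 kept, then differed by −1.27 to −0.81 percentage points.

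The number of lists past the threshold moved most. It was 3 with the preset correlation, 0 with an estimated correlation (adjusted p = 0.594 for each of the 3), and 6 with fry, which asks another question. It was 5 with DESeq2 size factors, 5 without the 5 most abundant miRNAs, 5 with TMM factors from outside the Dlk1-Dio3 list, 5 with thinned libraries, 7 without a filter, 3 without Mir127, and 3 to 5 with 1 library left out. The cause was not tested. The estimated correlation was 0.494 for the Dlk1-Dio3 list and 0.98 for the miR-183 cluster. For the Hox list it was −0.0343, which argues against members varying together as the cause of the lost call there. The p53-induced list had −0.0148, also under the preset 0.01, and its unadjusted camera p rose from 0.0494 to 0.112. The estimated setting thus raised p also in lists with an estimate under the preset value. An adjusted p of 0.594 is therefore no measure of how far members vary together. Under fry the Dlk1-Dio3 list had adjusted p = 0.0544. Over its 18 alternatives the Dlk1-Dio3 median stayed negative, from −0.59 to −0.32, with adjusted p from 5.9e-11 to 0.594.

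Nothing in the labels says that equal replicate numbers pair the libraries. Deviations from the group means correlated at −0.0566, 0.136 and 0.157 for numbers 1 to 3. For unequal numbers they correlated at −0.182 to 0.152, and so few values cannot settle whether libraries were paired. With the number as a replicate block, 76 miRNAs were called, 46 higher and 30 lower, 66 of them shared, and 3 lists.

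The values that changed sign were all uncalled, and the cause was not tested. The log2 fold change of Mir143 was 0.0253 with library totals, 0.0108 with upper quartile factors and 0.0208 with the stricter filter, and −0.0832 to 0.0367 with 1 library left out. The log2 fold change of Mir27b was 0.0103 with library totals and −0.28 to 0.0762 with 1 library left out. Under the factors from outside the Dlk1-Dio3 list, the log2 fold change of Mir148a was −0.0195, the log2 fold change of Mir128-1 was −0.0271 and the log2 fold change of Mir30a was −0.0976. Mir30a was −0.0011 with DESeq2 size factors and −0.00108 with the Wald test. The log2 fold change of Mir146 was 0.0539 with library totals, 0.0372 with upper quartile factors, 0.0204 without a filter, 0.0519 with the stricter filter, 0.0161 with limma-voom, 0.0153 with the replicate block, 0.0387 in each FPKM fit and 0.00565 with copies summed. With 1 library left out, Mir146 ranged from −0.17 to 0.13, Mir30a from −0.00808 to 0.0572, Mir128-1 from −0.0289 to 0.23, the log2 fold change of Mir322 from −0.0598 to 0.46 and the log2 fold change of Mir122 from −0.64 to 0.17. Depth limits rows such as Mir217 and Mir216a, whose WT libraries held 1 to 5 counts each.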

Other observations

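The tests of the rows at 0, of Mir127, of the Dlk1-Dio3 median over scalings, of the Dlk1-Dio3 median in other divisions of the libraries and of clusters without Mir216a and Mir217 were chosen after the result was seen. Neighbouring hairpins outside the Dlk1-Dio3 list had, on average, more similar fold changes than shuffled ones. The tested miRNAs formed 30 groups of 72 hairpins no more than 10000 bases apart on 1 strand, and the mean SD of log2 fold changes within groups was 0.2175, against 0.636 after shuffling (permutation p = 1e-05, the smallest that 100000 permutations can give). Without Mir216a and Mir217 it was 0.207 against 0.437 (permutation p = 1e-05). The groups with the largest mean changes were Mir216a with Mir217 (5.45), Mir182 with Mir96 and Mir183 (−1.91), Mir34b with Mir34c (0.88), Mir25 with Mir93 and Mir106b (0.84) and Mir15b with Mir16-2 (0.81). Some groups lay near that shuffled value of 0.437, such as Mir30b with Mir30d (SD 0.454), Mir201 with Mir547 (0.434), Mir194-2 with Mir192 (0.419) and Mir23a with Mir27a (0.404), and Mir216a with Mir217 had an SD of 0.517. The hypothesis that members of a group change without relation to each other is not borne out on average, which is consistent with changes at the level of shared transcripts for some groups. Host transcripts were not analysed here.

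With 3 libraries in each genotype there are 10 divisions of the 6 into 3 and 3, too few for a share under 0.05. The real one gave 72 changed miRNAs and the highest other gave 0 in the edgeR test, so 1 of the 10 was as large. At an unadjusted p under 0.05 the real one gave 101 and the highest other 12. Each other division holds both genotypes in both groups, so a genotype difference adds to the spread within groups and can lower these counts. The other divisions are thus no reference free of a genotype difference. For lists the real one gave 3 and the highest other 4, and 7 of the 10 were as large.

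The Dlk1-Dio3 cluster was lower in Fbxw7 KO. Over 5 scalings the cluster's median log2 fold change nearest to 0 was −0.4184, with library totals, and a scaling error, which cancels between miRNAs, cannot give the gap of −0.59 to the median of the other miRNAs (95% bootstrap interval −0.715 to −0.437, members treated as independent). With every library thinned to 2932439 counts the median was −0.52. Random thinning keeps the expected share of each miRNA, so this value cannot decide whether lower depth in the KO libraries played a part. A single library is argued against as the whole cause by a median of −0.3236 without Fbxw7 KO replicate 3, the value nearest to 0 over the 6 leave-outs. An effect of genotype stays open, as do embryos or cultures that differ in this imprinted region. Members vary together (estimated correlation 0.494), and the labels tie no library to an embryo. Use of the estimated correlation ended the call of this list. It also ended that of the Hox list, whose estimate was −0.0343, so a lost call alone does not show that members vary together.

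Many rows were at 0 in all 6 libraries, among them well-known miRNAs such as Mir22, Mir155, Mir17 and Mir126a. Rows that overlap another row were at 0 in 83.3% of 72 cases, against 39.2% of 1083 others (odds ratio 7.76, 95% interval 4.07 to 16, Fisher's exact p = 1.7e-13). Among rows without overlap, those sharing at least 20 bases with another row were at 0 in 52.6% of cases, against 36.1% of the 878 that share none (odds ratio 1.96, 95% interval 1.42 to 2.72, Fisher's exact p = 3.1e-05). Both are consistent with reads that were left out in counting, and no biological explanation was tested. For rows that overlap or share sequence, a 0 does not show that the miRNA was absent. The 36.1% at 0 among rows with neither is not accounted for by overlap or 20 shared bases with another annotated row. Copies outside the annotated rows were not looked for, so a loss of reads stays open there too.

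Mir127 in Fbxw7 KO replicate 3 had a log2 ratio of −3.897 to the mean of replicates 1 and 2. The 41 other tested members had a median of −0.41 (quartiles −0.543 and −0.213), so the cluster was also lower in that library. The size of that fall argues against it as the whole cause of the low Mir127. Its neighbours Mir433 and Mir434 stood at −0.07 and −0.67. Mir540 alone among the neighbours looked at was also far lower, at −2.58. A sequence variant or a library preparation effect on single hairpins was not tested and stays open, and no biological explanation was tested.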
